A study of Mus musculus with 29 samples.

How the data were processed

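H2Aub and H3K27me3 were measured by CUT&RUN in mouse oocytes and embryos of 29 libraries in 16 groups of 1 to 3, as the labels' titles give them. Per the submitters' processing notes, Trim Galore 0.4.5, Bowtie2 2.3.4.3, Picard 2.8.0 and deepTools 3.0.2 were used with the mm10 build. The table analysed here, which the authors deposited for the whole series, names itself a set of ChromHMM types of H2Aub. ChromHMM is a hidden Markov model that divides a genome into states from signal tracks. Its version, the libraries it was given, its bin size and the meaning of its types are not given in the sources used here. The deposited value is a type label from 1 to 5, a category and not a quantity, so no test of levels was made. Because the table is 1 segmentation with no column for any library, no library has a value, no replicate could be compared and the depth is unknown.

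All segment starts and ends were multiples of 5 kb, and a bin of 5 kb was used throughout. The segments tiled chromosomes 1 to 19 over 492539 bins. In 261 bins (0.053%) 2 segments overlapped, and there the shorter one was used. Gene positions, symbols and biotypes came from an NCBI RefSeq gene table of GRCm38.p6, the same build as mm10, with 49997 genes. The table gives no strand, so the planned assignment of genes by the base of the transcription start site could not be made. The type covering most of the gene body was used in its place. The table places 333 genes (107 protein-coding) on separate scaffolds with positions counted from the scaffold's start, and these were left out, a choice made after the data had been examined. That left 46709 genes on the segmented chromosomes, 20558 of them protein-coding. Of the protein-coding genes, 68.7% lay wholly in 1 type, 76.0% had at least 90% of the body in 1 type, and 346 had no type over 50%.

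Segment lengths were compared by the median between pairs of types with 100000 permutations of the type labels. Borders were counted between segments next to each other and compared with 10000 shuffles of the types within chromosomes. As an alternative added after the results were seen, the shuffles were restricted to orders in which no neighbours were of 1 type, made by random swaps within chromosomes. Gene shares were compared with 10000 circular shifts of the genes within chromosomes. Shares of chromosomes were correlated with protein-coding genes per Mb by Pearson's r and Spearman's rho with 100000 permutations. Gene lists were compared with all other protein-coding genes by Fisher's exact test, with Benjamini-Hochberg adjustment over all 95 pairs of 19 lists and 5 types. All tests were two-sided, adjustment was by Benjamini-Hochberg within each family, and the threshold was an adjusted p of 0.05. Intervals of shares are exact 95% Clopper-Pearson intervals.

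The lists were Hox cluster genes, developmental transcription factors outside Hox clusters, secreted developmental ligands, imprinted genes with oocyte H3K27me3, imprinted genes with DNA methylation, oocyte genes, 2-cell stage genes, pluripotency genes, trophectoderm genes, primitive endoderm genes, germline genes, ribosomal protein genes, proteasome subunit genes, Polycomb complex genes, keratin genes, protocadherin cluster genes, olfactory receptor genes, vomeronasal receptor genes and zinc finger protein genes. The last 3 were taken by symbol, and the others were written out by name. Members were matched by symbol or synonym, and only protein-coding genes on the segmented chromosomes entered the tests. Names with no match on those chromosomes, such as Xist, Cdx4, Esx1 and Rhox5, were not analysed here. Bmp4 and other genes stand in more than 1 list.

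The lists, tests, alternatives and the rule for naming genes were set before the data were examined. By that rule the text names, for each list past the threshold in a type, the first 4 members in alphabetical order that hold the type. It also names, from the 10 genes per type with the largest part of the window in that type, those of longest body, from the 5 longest segments per type those with their genes, and 14 fixed genes. The window around the start site was replaced by the gene with 20 kb on each side. Where a member outside the rule is named in a count of 5 or fewer, the text says so. Some genes that the rule takes are not reported here.

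Settings varied by prior choice were merged segments, mean length, shares of the number of segments, touching segments only, all annotated genes, list genes within 100 kb of each other counted once, and 10000 circular shifts of the lists. Settings added after the data were examined were the longer segment in overlaps, chromosomes without their gene-free starts, segments of at least 25 kb, and gene types by the middle bin or by the bin at either end. Also added were the body with 5 kb on each side, only genes with at least 90% of the body in 1 type, all annotated genes for the lists, 10000 rotations of each list along the gene order, and keeping the genes placed on scaffolds. Shifts in the alternatives for all genes numbered 1000. Circular shifts set a list beside the same genes at shifted positions, so their baseline is not the share of other genes.

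The tests were tested on simulated data. For lists planted in the 20558 genes, none of 60 lists of 50 genes with no effect was called, at an odds ratio of 4 58 of 60 lists of 50 genes were, and at an odds ratio of 2 10 of 60 were. For lists of 20 genes at an odds ratio of 4, 32 of 60 were called, so a list of that size can miss such an effect. Members of these lists were drawn independently, so the simulations do not cover lists whose genes lie in clusters. A length ratio of 1.5 between 1500 segments each was called in 40 of 40 simulations and a ratio of 1 in 1 of 40. In 20 simulations of 31563 segments, planted borders were called in 20, and 2 of 20 simulations without them gave a call. With shuffles of unlike neighbours, planted borders were called in 20 of 20 and 1 of 20 without them. For 300 genes drawn at random the type coverage was checked against a direct count, and all 300 matched. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.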

Results

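Monoubiquitinated histone H2A (H2AK119ub, here H2Aub), the mark laid down by Polycomb repressive complex 1, was profiled by CUT&RUN, in which a nuclease tethered to an antibody releases the DNA around the mark. Of 29 mouse libraries in 16 groups, 24 measured H2Aub and 5 measured H3K27me3, the mark of Polycomb repressive complex 2. Wild-type H2Aub was measured in 16 libraries from 8 stages: germinal vesicle oocytes (2), metaphase II oocytes (2), zygotes (2), 2-cell (3), 4-cell (2) and morula embryos (2), inner cell mass (1) and E6.5 epiblast (2). Another 6 H2Aub libraries came from oocytes, 4-cell embryos and morulae lacking maternal Eed, a core subunit of Polycomb repressive complex 2, with 2 libraries each. At the 4-cell stage 6 libraries came from PR-DUB control and overexpression embryos, PR-DUB being the deubiquitinase of H2A. Their groups held 1 H2Aub and 2 H3K27me3 libraries each, and 1 H3K27me3 library came from wild-type germinal vesicle oocytes. Libraries held 1 to 300 oocytes or embryos, and 3 libraries carried no number.

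The values analysed here were 1 genome segmentation, in which every stretch of chromosomes 1 to 19 carried an H2Aub type from 1 to 5. The types had no key, so they are given by number, and no level of H2Aub is attached to any of them. The segmentation held no value per library. Read depth is therefore unknown, and the comparisons that the design implies between stages, between Eed genotypes and between PR-DUB groups were not analysed here. The comparisons below ask which regions and genes lay in which type. Their p-values measure chance placement of segments, genes and lists along 1 segmentation, not the spread between libraries. Coordinates are counted from 1 on mm10.

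Type 1 covered the most sequence and type 2 the least. The longest type 5 segment, which was also the longest of all, was 11.205 Mb of chromosome 14 (87585001 to 98790000) with 5 protein-coding genes, among them the cell adhesion genes Pcdh9 and Pcdh20 and the transcription factor gene Dach1. Next in type 5 came 7.375 Mb of chromosome 16 (65280001 to 72655000) with the adhesion gene Cadm2 and the pituitary factor gene Pou1f1, and 5.875 Mb of chromosome 16 (78645001 to 84520000) with Ncam2. The longest type 4 segments with genes wholly inside lay around Gli2, a Hedgehog pathway factor, and Inhbb, an inhibin subunit (chromosome 1, 118755001 to 119520000, 0.765 Mb), and around Maf (chromosome 8, 115075001 to 115795000, 0.72 Mb). The longest type 3 segment spanned 0.785 Mb on chromosome 2 (71840001 to 72625000) with Rapgef4, Pdk1, Map3k20 and Cdca7. In type 1, 5.92 Mb at the start of chromosome 14 held 44 protein-coding genes, and 3.37 Mb of chromosome 7 (19970001 to 23340000) held 86, many of them Vmn1r pheromone receptor genes.

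The 31563 segments covered 2462.7 Mb. Type 1 took 32.1% of the length in 7945 segments, type 5 24.0% in 3775, type 3 19% in 9092, type 4 13.6% in 4751 and type 2 11.2% in 6000. Over the 19 chromosomes the SD of these shares was 3.72 percentage points for type 1, 7.18 for type 5, 3.95 for type 3, 3.32 for type 4 and 2.00 for type 2. Segments of 1 Mb or more numbered 92 in type 5, 47 in type 1 and 2 in type 2, and types 3 and 4 had none. The first segment of each of the 19 chromosomes was type 1, and of the 58.19 Mb before the first annotated gene of the chromosomes, 99.3% was type 1. These first segments were at least 2.99 Mb long, so all 19 are among the 47 type 1 segments of 1 Mb or more. Without the gene-free starts type 1 took 30.5% of the length.

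Over all protein-coding genes the median gene length was 34.5 kb in type 2, 22.8 kb in type 1, 17.9 kb in type 4, 13.7 kb in type 3 and 7.14 kb in type 5. Of the 1960 genes in type 5, 614 were olfactory and 78 vomeronasal receptor genes, and the median without them was not taken. Genes lying wholly in 1 type can be no longer than its segments, the longest of which was 11.2 Mb in type 5, 5.92 Mb in type 1 and 1.05 Mb or less in the others. The longest genes lying wholly in type 5 with 20 kb on each side were the axon guidance receptor gene Robo2 (1555 kb) and the synaptic adhesion gene Lrrc4c (1314 kb), followed by Sgcz, Cadm2, Pcdh9 and Dpyd. In type 1 they were the laminin gene Lama2 (635.9 kb), Spock3, Plxdc2 and Dnah7c. In type 4 they were the splicing factor gene Rbfox3 (421.8 kb), the Notch coactivator gene Maml3 (418.0 kb), Gabbr2 and Kif6. In type 2 they were Ldb2 (363.8 kb), the epidermal regulator Trp63 (208.3 kb) and Lrrtm3, and in type 3 Rapgef4 (276.3 kb), Ctif and Mical3.

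Median segment length was 50 kb for type 1, 45 kb for type 5, 40 kb for type 4, 30 kb for type 3 and 25 kb for type 2. Over the 10 pairs of types, two-sided permutation tests with 100000 shuffles of the type labels gave an adjusted p of 1.43e-05 for 7 pairs, from the smallest p possible, 1e-05. Types 1 and 5 differed by 5 kb (permutation p = 0.0155, adjusted p = 0.0194). Types 2 and 3 (permutation adjusted p = 0.937) and types 4 and 5 (adjusted p = 0.965) did not pass. Both pairs differed by 5 kb, 1 step of the lengths, which most shuffles also reached, so the median test cannot decide on them. Their means differed, at 46.2 kb for type 2 against 51.6 kb for type 3 and 70.6 kb for type 4 against 156 kb for type 5 (permutation adjusted p = 1e-05 each). By mean length type 5 segments (156 kb) were longer than type 1 segments (99.7 kb), the opposite order to the medians.

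Chromosome 16 held the largest share of type 5, 43.5% of its length, and the smallest shares of types 1 (22.3%) and 4 (8.04%). Chromosome 11, which carries the Hoxb cluster and a keratin cluster, held the least type 5 (9.93%) and the most of types 3 (26.7%) and 4 (20.3%). Protein-coding genes lay at 6.91 per Mb on chromosome 16 and 13.1 per Mb on chromosome 11. Of the 5 longest type 5 segments, 3 were on chromosome 16. Across chromosomes, types 3 and 4 took larger shares where genes were denser, and types 2 and 5 smaller ones. The X chromosome, which the design set beside the autosomes, was not analysed here.

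Over the 19 chromosomes and 5 types, each share was correlated with protein-coding genes per Mb by two-sided permutation tests. For type 3, Pearson's r was 0.672 (p = 0.00176, adjusted p = 0.00293) and Spearman's rho 0.714 (p = 0.00091, adjusted p = 0.00227). For type 4, r was 0.742 (p = 0.00034, adjusted p = 0.00085) and rho 0.653 (p = 0.00316, adjusted p = 0.00527). For type 2, r was -0.749 (p = 1e-04, adjusted p = 5e-04) and rho -0.726 (p = 0.00084, adjusted p = 0.00227). For type 5, r was -0.586 (p = 0.00841, adjusted p = 0.0105) and rho -0.565 (p = 0.0126, adjusted p = 0.0157). Type 1 did not pass, with r 0.157 (p = 0.524, adjusted p = 0.524) and rho 0.125 (p = 0.612, adjusted p = 0.612). Without chromosomes 7 and 11, the farthest from the median density, r was 0.695 for type 3, 0.510 for type 4, -0.677 for type 2, -0.375 for type 5 and -0.0732 for type 1. With shares of the number of segments in place of length, the type 5 relation did not pass (rho = -0.304, adjusted p = 0.257).

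Segments of types 4 and 5 bordered each other, as at Smoc1, an imprinted gene for a matricellular protein, where a 10 kb type 5 segment lay between type 4 segments of 135 and 220 kb. At Gab1, an imprinted signalling adaptor gene, a 200 kb type 4 segment lay between type 5 segments of 90 and 85 kb. Around the Hoxd cluster, by contrast, types 4, 3 and 1 followed each other on one side and types 4, 3, 2 and 1 on the other. Types 1 and 4 met at only 192 borders.

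Types 4 and 5 met at 3610 borders, 11.4% of all, 2.49 times the mean of 10000 shuffles of the types within chromosomes (4.61%). These shuffles place segments of 1 type side by side, which the segmentation did at only 12 places, so a ratio of 1 is not their value for types with no preference. Ratios were therefore also taken, after the results were seen, to 10000 shuffles in which neighbours always differed in type. Against these, types 4 and 5 met 3.24 times as often, types 1 and 2 1.38 times, types 3 and 4 1.26 times and types 1 and 3 1.16 times (1.35, 1.3 and 1.40 times for the last 3 pairs in the first shuffles). Ratios below 1 were 0.658 for types 2 and 5, 0.574 for types 2 and 4, 0.274 for types 3 and 5 and 0.0682 for types 1 and 4 (0.537, 0.478, 0.272 and 0.0628 in the first shuffles). These 8 pairs gave p = 2e-04 in both two-sided permutation tests, the smallest possible. Types 1 and 5, at 0.903 in the first shuffles, were at 1.003 where neighbours differed (permutation adjusted p = 0.838). Types 2 and 3 turned from 1.05 to 0.979 (permutation adjusted p = 0.0187), so neither pair had a departure that held in both.

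**Figure D1:**
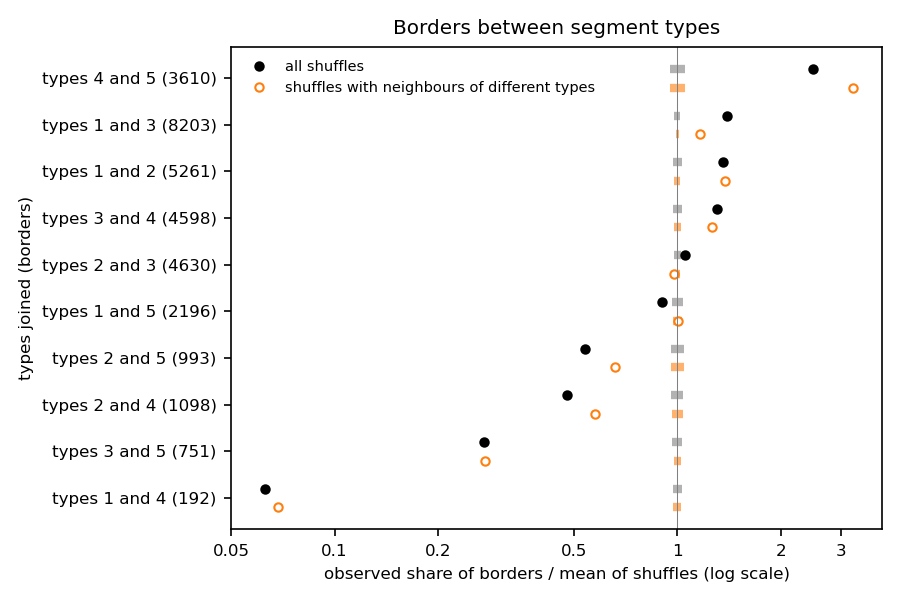
The x axis is the observed share of borders joining 2 types divided by its mean over shuffles, on a log scale, and each line is a pair of types with its number of borders. Black points are ratios to all shuffles and open orange points to shuffles with neighbours of different types, and grey and orange bars span 95% of each; types 4 and 5 lie at 2.49 and 3.24, types 1 and 4 at 0.0628 and 0.0682, and types 1 and 5 at 0.903 and 1.003.

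Protein-coding genes lay mostly in types 1 and 3. Gapdh, a glycolytic enzyme gene, lay in type 1, and the transcription factor genes Gata6 and Pou5f1 lay wholly in type 3. Pax6, a regulator of eye and brain development, lay in type 3 over 96.3% of its body. Actb, the cytoplasmic actin gene, was 61.2% type 3 and 38.8% type 1. Nanog, a pluripotency regulator, lay wholly in type 5.

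Of 20558 protein-coding genes, each given the type covering most of its body, 7645 (37.2%) took type 1, 6947 (33.8%) type 3, 2888 (14.0%) type 4, 1960 (9.53%) type 5 and 1118 (5.44%) type 2. In 10000 circular shifts of the genes within their chromosomes the mean shares were 32.6%, 19.6%, 14.4%, 22.9% and 10.5% in the same order. Genes were thus found in type 3 at 1.72 times and in type 1 at 1.14 times the shifted share, in type 5 at 0.415 times and in type 2 at 0.520 times (two-sided permutation p = 2e-04 each, the smallest possible, adjusted p = 0.00025). Type 4 did not differ (0.977 times, permutation adjusted p = 0.624). The excess in type 1, 4.57 percentage points, was 0.975 and 0.654 points by the bins at the lower and higher gene ends and 0.567 points over all annotated genes (permutation adjusted p = 0.5, 0.707 and 0.482). Over all annotated genes type 4 was 1.87 points above the shifts (permutation adjusted p = 0.0025).

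**Figure D2:**
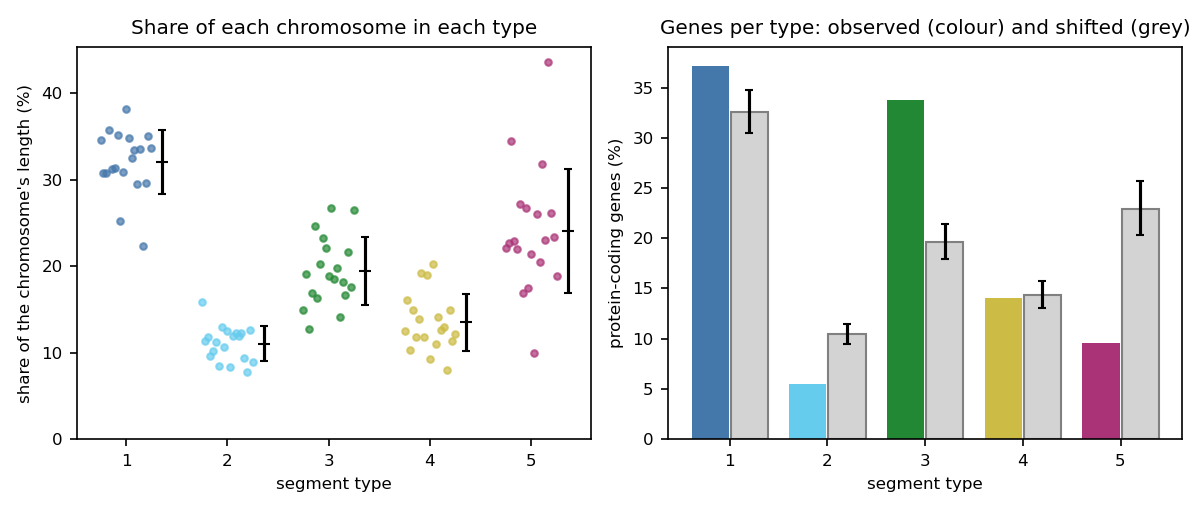
The left panel shows the share of each chromosome's length in each type (%, 1 point per chromosome), with the mean and SD over 19 chromosomes beside the points. The right panel shows the share of protein-coding genes in each type (coloured bars) and its mean over circular shifts (grey bars, error bars 95% of shifts); type 3 holds 33.8% against 19.6% and type 5 9.53% against 22.9%.

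The Hox clusters, which pattern the body axis, lay in type 4 with parts in type 3. On chromosome 6, Hoxa9, Hoxa10, Hoxa11 and Hoxa13 lay wholly inside a type 4 segment of 280 kb. The Hoxd cluster (chromosome 2, 74668225 to 74765142), with Hoxd10, was 99.9% type 4, in a segment of 125 kb. The Hoxc cluster (chromosome 15, 102921131 to 103036856) changed from type 4 to type 3 at position 103000001, and the Hoxb cluster (chromosome 11, 96194316 to 96368254) was 57.9% type 4 and 42.1% type 3. In type 3 were Hoxb1, Hoxb2, Hoxc4 and Hoxc5, with Hoxc6, a member named after its value was seen.

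Of 39 Hox genes, 34 lay in type 4 (87.2%, 95% Clopper-Pearson interval 72.6 to 95.7%) against 13.9% of other protein-coding genes (two-sided Fisher's exact test, adjusted p = 3.34e-23 over the 95 pairs of 19 lists and 5 types). With clustered genes counted once, 4 of 4 lay in type 4 (Fisher's exact adjusted p = 0.00274). None lay in type 1 (exact adjusted p = 1.38e-07) and 5 lay in type 3 (12.8%, adjusted p = 0.0173, below other genes). With clusters counted once neither type held any of the 4, a difference of -37.3 points for type 1, as before, and of -33.8 for type 3, from -21.0. On 4 clusters neither passed (exact adjusted p = 0.456). With clusters kept whole, neither passed by circular shifts (permutation adjusted p = 0.131 for type 1 and 0.905 for type 3). By rotations along the gene order type 1 passed (permutation adjusted p = 0.00528) and type 3 did not (0.213). The intervals of all lists cover counting error only, and genes of a cluster are not independent.

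**Figure D3:**
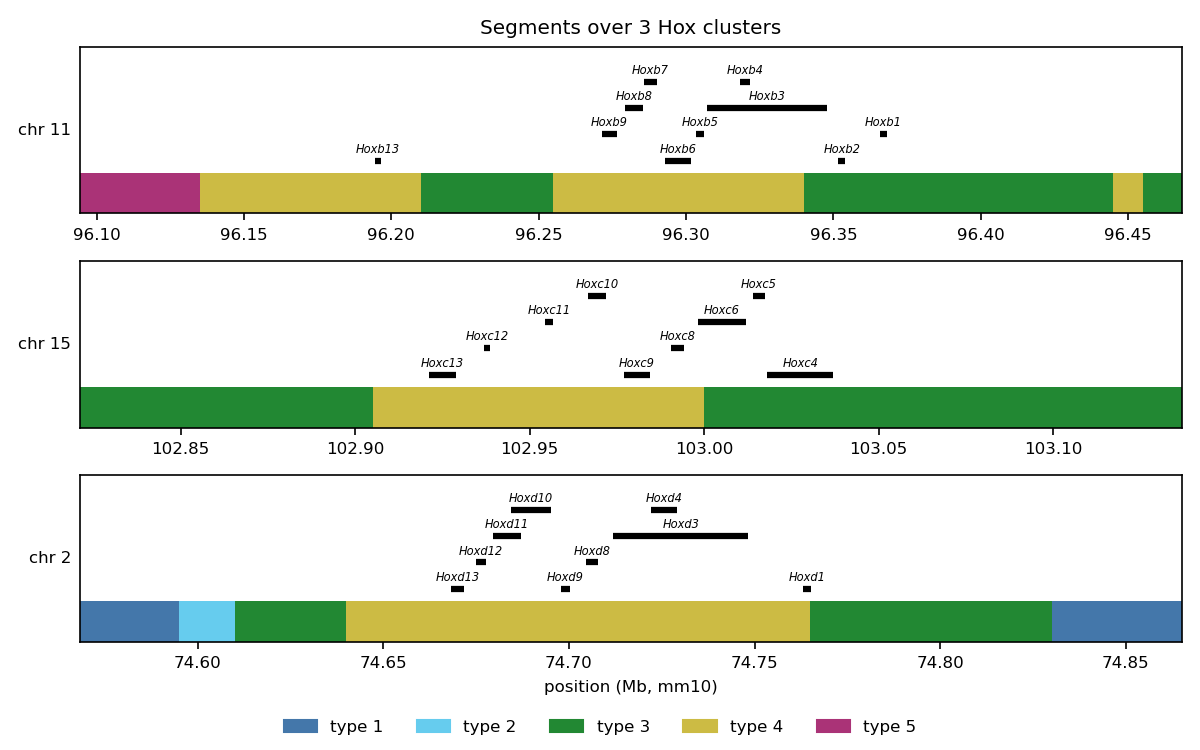
The x axis of each panel is the position (Mb, mm10) over the Hoxb, Hoxc and Hoxd clusters with 100 kb on each side, from top to bottom. Coloured bars are segments by type and black lines are genes; the Hoxd cluster is 99.9% type 4, and Hoxb1, Hoxb2, Hoxc4 and Hoxc5 lie in type 3.

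Developmental transcription factors outside the Hox clusters lay in type 4 more often than other genes. In type 4 were the homeobox genes Alx4, Barhl1 and Barx1, each wholly. In type 5 were Alx1, Meox2, Neurod1 and Sim1, with Tbx18, which was named after its value was seen. Among secreted ligands, Bmp2, Bmp7, Cer1 and Fgf15 lay in type 4, Bmp4, Bmp6 and Chrd, a Bmp antagonist, in type 3, and Bmp5 in type 1 over 72.3% of its body. Bmp3 was 50.6% type 3 and 47.4% type 2.

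Of 143 such factors, 77 lay in type 4 (53.8%, interval 45.3 to 62.2%) against 13.8% of other genes (exact adjusted p = 5.96e-28), 60 in type 3 (42.0%, adjusted p = 0.0785), 1 in type 1 (adjusted p = 2.23e-26), 5 in type 5 (adjusted p = 0.0252) and 0 in type 2 (adjusted p = 0.00213). The last 3 shares were below those of other genes, and that in type 5 was not past the threshold with clusters counted once (exact adjusted p = 0.0785), at -5.76 points against -6.08. Of 50 ligands, 26 lay in type 3 (52.0%, interval 37.4 to 66.3%, against 33.7%, exact adjusted p = 0.0259) and 18 in type 4 (36%, interval 22.9 to 50.8%, against 14.0%, adjusted p = 0.000341). In type 1 there was 1 ligand, below other genes (exact adjusted p = 1.95e-08). The type 3 share of ligands was past the threshold under 4 of 10 alternatives. Circular shifts were among these, but their baseline for type 3 is lower than that of other genes. All protein-coding genes were 33.8% type 3 against 19.6% at shifted positions. With clusters counted once 22 of 42 lay in type 3 (52.4%, exact adjusted p = 0.0547), so there the call ended with the number of genes and not with a smaller share. The excess, 18.3 points, fell to 9.94 by the lower gene end, 15.8 by the higher end and 15.9 with 5 kb on each side (exact adjusted p = 0.289, 0.072 and 0.0575). It was 18.2 points by rotations and 19.2 with only genes at least 90% in 1 type, also not past the threshold.

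Genes imprinted through H3K27me3 inherited from the oocyte lay mainly in type 4. Smoc1 was 93.7% type 4, Gab1 90.9%, Jade1, a histone acetylation cofactor gene, 72.4% and the amino acid transporter gene Slc38a4 65.7%. Sfmbt2, a Polycomb protein gene (chromosome 2, 10370440 to 10595253), was split over 8 segments: 49.0% type 5, 33.2% type 4, 13.3% type 1 and 4.45% type 3. Of genes imprinted through DNA methylation, the trophoblast factor gene Ascl2, the cell cycle inhibitor gene Cdkn1c and the deiodinase gene Dio3 lay wholly in type 4, and Ddc, an amine synthesis gene, over 77.3% of its body.

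Of the 5 genes with oocyte H3K27me3, 4 took type 4 (80.0%, interval 28.4 to 99.5%; Fisher's exact adjusted p = 0.00565). By the bin at the higher gene end the difference fell from 66 to 25.6 points and the call was lost (exact adjusted p = 0.27). With only genes that had at least 90% of the body in 1 type, Gab1 and Smoc1 were left, both in type 4, and the call ended with a difference of 86.2 points (exact adjusted p = 0.053). Of 37 protein-coding genes imprinted by DNA methylation, 13 lay in type 4 (35.1%, interval 20.2 to 52.5%, against 14.0%, exact adjusted p = 0.00359), 10 in type 3, 8 in type 1, 4 in type 2 and 2 in type 5. Their excess in type 4, 21.1 points, was 18.6 points by circular shifts (permutation adjusted p = 0.0821) and 10 and 9.95 by the bins at the lower and higher gene ends (exact adjusted p = 0.176 and 0.182), none past the threshold.

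**Figure D4:**
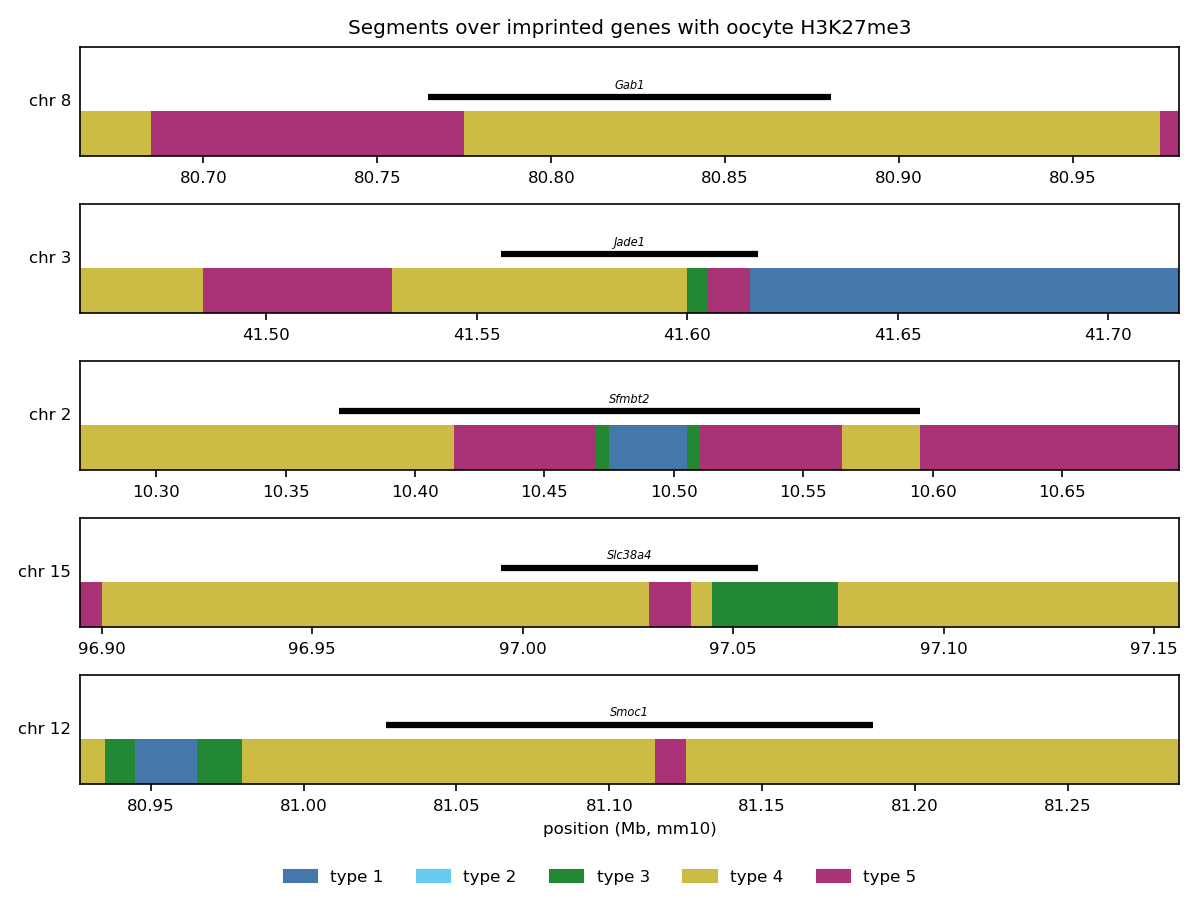
The x axis of each panel is the position (Mb, mm10) over Gab1, Jade1, Sfmbt2, Slc38a4 and Smoc1 with 100 kb on each side, from top to bottom. Coloured bars are segments by type and the black line is the gene; Smoc1 is 93.7% type 4, and Sfmbt2 crosses 8 segments of types 1, 3, 4 and 5.

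Genes of the oocyte and of the trophectoderm, the outer layer of the blastocyst, lay in type 3 more often than other genes, with limits given beside the counts. The oocyte genes in type 3 included Astl, whose protease cleaves the egg coat, Bcl2l10, the deadenylation factor gene Btg4 and Dppa3, which protects the maternal genome from demethylation, each wholly. The trophectoderm genes in type 3 included Cdx2, a regulator of that lineage, the water channel gene Aqp3, Bmp4 and Cdh3 (74.1% of its body). Dppa1 and Lrp2 were the trophectoderm list's members in type 1, and Cubn and Dab2 those of the primitive endoderm list.

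Of 43 oocyte genes, 23 lay in type 3 (53.5%, interval 37.7 to 68.8%, exact adjusted p = 0.0246), 18 in type 1, 1 in type 4, 1 in type 2 and 0 in type 5. Of 22 trophectoderm genes, 14 lay in type 3 (63.6%, interval 40.7 to 82.8%, exact adjusted p = 0.0166) and 2 in type 1 (9.09%, adjusted p = 0.0182, below other genes). Of 22 primitive endoderm genes, 10 lay in type 3, 7 in type 4 (exact adjusted p = 0.0575) and 2 in type 1 (adjusted p = 0.0182, below). The type 1 shares of both lists were past the threshold under 8 of 10 alternatives, but not by circular shifts (permutation adjusted p = 0.0626 each). By the bin at the higher gene end the type 3 excesses of oocyte genes (15.3 points, from 19.7) and trophectoderm genes (25.4, from 29.9) were not past the threshold (exact adjusted p = 0.0921 and 0.0694). Nor was that of oocyte genes with only genes at least 90% in 1 type (19.4 points, exact adjusted p = 0.0556). Pluripotency genes (28: 9 in type 1, 6 in type 3, 8 in type 4, 5 in type 5) had no share past it, the lowest adjusted p being 0.0893. Nor did germline genes (43: 17 in type 1, 19 in type 3; lowest 0.197) or Polycomb complex genes (34: 17 in type 1, 14 in type 3; lowest 0.126).

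Genes switched on at the 2-cell stage lay in type 1 more often than other genes, among them Gm4340, Gm8300, B020031M17Rik and Pramel11. Genes needed in every cell did so too: the ribosomal protein genes Fau, Rpl11, Rpl13 and Rpl13a and the proteasome subunit genes Psma1, Psma2, Psma3 and Psma4 lay wholly in type 1. Zinc finger protein genes, such as Zfp106 and Zfp110, were in type 1 more often than other genes. The gene-free chromosome starts, 99.3% type 1, are a measured limit beside lists with near-identical copies, such as the 2-cell stage genes.

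Of 28 2-cell stage genes, 23 lay in type 1 (82.1%, interval 63.1 to 93.9%, against 37.1%, exact adjusted p = 6.71e-06), 4 in type 3 and 1 in type 2, Duxf3, named after its value was seen. Of 75 ribosomal protein genes, 54 lay in type 1 (72.0%, interval 60.4 to 81.8%, exact adjusted p = 6.97e-09) and 0 in type 4 (adjusted p = 7.73e-05). Of 31 proteasome genes, 23 lay in type 1 (74.2%, interval 55.4 to 88.1%, exact adjusted p = 0.000178) and 0 in type 4 (adjusted p = 0.0402, and 0.0644 with clusters counted once, where all 31 were still counted). Of 388 zinc finger genes, 217 lay in type 1 (55.9%, interval 50.8 to 60.9%, exact adjusted p = 4.46e-13). Their shares in type 2 (7 genes, exact adjusted p = 0.00213), type 4 (38, adjusted p = 0.0358) and type 5 (16, adjusted p = 0.000314) were below those of other genes. With 216 clusters the differences were -3.19 points in type 2 (from -3.70), -1.63 in type 4 (from -4.34) and -4.08 in type 5 (from -5.51), none past the threshold (exact adjusted p = 0.101, 0.695 and 0.121).

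Olfactory receptor genes lay in type 5 more often than other genes, for example Olfr1 and Olfr10 on chromosome 11 and Olfr1000 and Olfr1002 on chromosome 2. Vomeronasal receptor genes, which detect pheromones, lay in type 1 more often, among them Vmn1r100, Vmn1r101 and Vmn1r103 on chromosome 7. Others, such as Vmn1r10 and Vmn1r11 on chromosome 6, lay in type 5. Keratin genes of stratified epithelia, Krt1, Krt13, Krt14 and Krt15, lay wholly in type 4. Of the clustered protocadherins, neuronal adhesion genes on chromosome 18, Pcdha1 to Pcdha4 were 51.1% to 55.3% type 4 with the rest in type 5, and Pcdha5 and Pcdha10 to Pcdha12 were 50.6% to 68.7% type 5. The bodies of these Pcdha genes overlap, starting at 36930285 to 37020230 and ending at 37187657 to 37187663. Much of the same sequence thus enters the type of each.

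Of 1103 olfactory receptor genes, 614 lay in type 5 (55.7%, interval 52.7 to 58.6%) against 6.92% of other genes. The share was also above that of the same genes at shifted positions (circular shifts, permutation adjusted p = 0.000864), a baseline other than the 6.92%. Only 49 lay in type 3 (4.44%, exact adjusted p = 4.44e-130), and types 1 (335 genes, 30.4%, adjusted p = 6.39e-06), 2 (42, adjusted p = 0.0344) and 4 (63, adjusted p = 1.76e-18) were also below other genes. With clusters counted once, 18 of 77 lay in type 5 (23.4%), 16.5 points above other genes, from 48.7 (Fisher's exact adjusted p = 5.17e-05). More of the 77 clusters lay in type 1 (34, 44.2%). Type 1 turned from -7.20 to 6.58 points above other genes, type 2 went from -1.72 to -4.23 and type 4 from -8.81 to -1.53. The shares in types 1, 2 and 4 were then not past the threshold (Fisher's exact adjusted p = 0.393, 0.27 and 0.997). Of 351 vomeronasal receptor genes, 251 lay in type 1 (71.5%, interval 66.5 to 76.2%, against 36.6%, exact adjusted p = 6.17e-38) and 78 in type 5 (22.2%, interval 18.0 to 26.9%, against 9.31%, adjusted p = 8.02e-12, but 1.06 points above the shifts by circular shifts, adjusted p = 0.91). Types 3 (4 genes, exact adjusted p = 7.13e-55) and 4 (4 genes, adjusted p = 4.84e-17) were below other genes. Reads lost in near-identical copies were not tested for vomeronasal receptor genes. Type 1 was also the type of 99.3% of the gene-free chromosome starts.

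Of 40 keratin genes, 27 lay in type 4 (67.5%, interval 50.9 to 81.4%, exact adjusted p = 1.53e-13), 13 in type 3 and 0 in type 1 (adjusted p = 7.97e-08). With clusters counted once both calls were lost: 1 of 4 lay in type 4, a difference of 11.1 points against 53.6 (Fisher's exact adjusted p = 0.613), and 0 of 4 in type 1, with the difference still -37.3 points (exact adjusted p = 0.456). With clusters kept whole, the type 4 call held by circular shifts (permutation adjusted p = 0.037) and by rotations along the gene order (permutation adjusted p = 0.00335). Of 46 protocadherin genes, with overlapping Pcdha bodies each counted as a gene, 29 lay in type 4 (63.0%, interval 47.5 to 76.8%, exact adjusted p = 2.19e-13) and 11 in type 5 (23.9%, adjusted p = 0.0105). Types 1 (2 genes, exact adjusted p = 1.49e-06) and 3 (4 genes, adjusted p = 0.000467) were below other genes. With clusters counted once only 2 remained, both in type 4, and no call held with so few (exact adjusted p = 0.071, 1, 0.693 and 0.695 in that order). The difference was then 86.1 points in type 4 (from 49.1), -37.3 in type 1 (from -32.9) and -33.8 in type 3 (from -25.2), and type 5 turned from 14.4 to -9.50. With clusters kept whole, the type 4 call held by rotations (permutation adjusted p = 0.00855) and was not past the threshold by circular shifts (51.7 points, permutation adjusted p = 0.0821). The calls in types 1, 3 and 5 held by neither (permutation adjusted p = 0.607, 0.965 and 0.905 by circular shifts and 0.0676, 0.334 and 0.396 by rotations). In all, 18 of the 95 pairs of list and type were above other genes at an adjusted p under 0.05 and 22 were below.

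**Figure D5:**
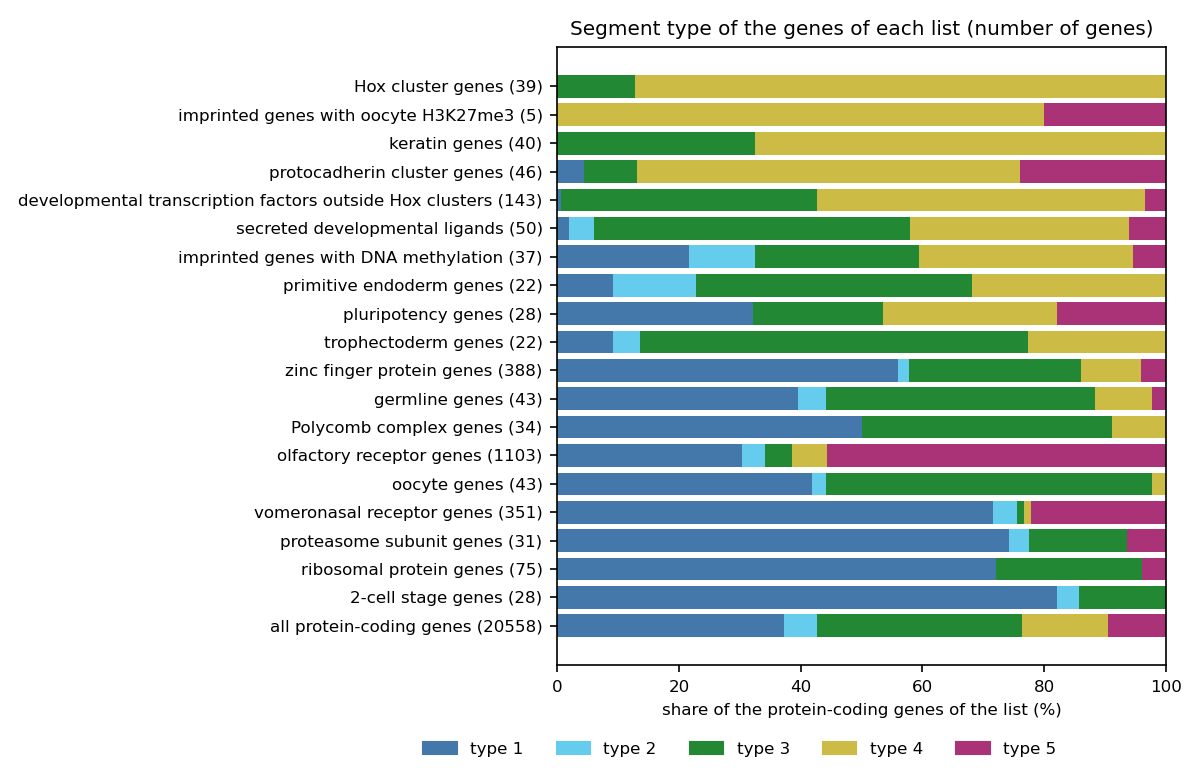
Each bar is a gene list with its number of protein-coding genes, and the x axis is the share of its genes (%) in each type, with all 20558 protein-coding genes at the bottom. Hox genes are 87.2% type 4, olfactory receptor genes 55.7% type 5 and 2-cell stage genes 82.1% type 1.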

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

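The tests chosen only after the results were seen were those with segments of at least 25 kb, the longer segment in overlaps, gene-free starts left out, genes typed by their middle or end bins, by the body with 5 kb on each side or only where 90% was in 1 type, list rotations, all annotated genes for lists, scaffold genes kept, and shuffles with neighbours of different types. In those shuffles the border ratio was reversed to 1.003 for types 1 and 5 and to 0.979 for types 2 and 3, since the first shuffles allow neighbours of 1 type; the other 8 pairs kept direction and threshold. With segments of at least 25 kb, type 2 had 3020 segments and type 3 had 5583, since short segments were dropped. By mean length, type 1 minus type 5 was reversed at -56.7 kb. Type 2 minus type 3 was -5.39 kb and type 4 minus type 5 was -85.9 kb, both now past the threshold. The mean gives weight to the longest segments, but between types 2 and 3 the longest was in type 2 (1.05 against 0.785 Mb). Their lower and upper quartiles were 10 and 55 kb in type 2 and 15 and 65 kb in type 3. The excess of genes in type 1 was 0.975 points by the lower gene end, 0.654 by the higher end and 0.567 over all annotated genes, none past the threshold. Type 4, not past it in the main test, turned to 0.0516, 0.132 and 1.87 points above the shifts in the same order, and the cause was not tested. Pairs of list and type below other genes fell from 22 to 9 with clusters counted once, where fewer genes were counted, and to 13 by rotations, for which the cause was not tested. Over all 10 alternatives 14 to 18 pairs were above other genes and 9 to 29 below. By circular shifts the comparison was with shifted positions in place of other genes. By the number of segments, rho with gene density was -0.0965 for type 1 (reversed) and -0.304 for type 5 (not past the threshold), and the cause was not tested. The protocadherin share in type 5 turned to -9.50 points with clusters counted once and to -0.572 by the lower gene end. Of the 18 pairs above other genes, 9 held under all 10 alternatives: Hox, developmental factor and ligand genes in type 4, 2-cell stage, ribosomal, proteasome, vomeronasal and zinc finger genes in type 1 and olfactory receptor genes in type 5. No alternative tested reads lost in near-identical copies. No paired analysis was possible because the segmentation held no value per library, although groups share replicate numbers. Not run were start-site bases and windows of 1 kb and 5 kb around them (no strand) and sequence composition (no genome used here); leaving out segments under 5 kb or chromosomes other than autosomes removed nothing. Depth was unknown, so what it limits could not be stated.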

Other observations

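The tests of gene families, of gene biotypes and of receptors by chromosome, the rotations along the gene order, and the test of olfactory receptor genes standing alone, were chosen only after results were seen. Families that share a symbol stem and have at least 25 protein-coding genes also differed between types. Of 26 prolactin family genes (Prl), placental hormones of the mouse, 21 lay in type 5 (80.8%, 95% Clopper-Pearson interval 60.6 to 93.4%), as did 36 of 56 hair keratin-associated protein genes (Krtap, 64.3%) and 26 of 38 Tas genes, mostly taste receptors (68.4%). The alpha-defensin genes (Defa), antimicrobial peptides of the gut, lay in type 1 in 29 of 29 cases, and so did 36 of 45 Pramel genes (80.0%) and 39 of 53 translation initiation factor genes (Eif, 73.6%). The beta-defensins (Defb) stood apart, with 14 of 42 in type 2 (33.3% against 5.38% of other genes). Collagen genes (Col) lay in type 4 in 16 of 42 cases (38.1%) and kallikreins (Klk) in 16 of 26 (61.5%), while 175 of 362 solute carrier genes (Slc, 48.3%) lay in type 3. By rotations of each family along the gene order, adjusted over 365 pairs of 73 families and 5 types, Defb, Eif and Slc had an adjusted p of 0.00384, Krtap 0.00608, Col 0.014, Pramel 0.0354 and Tas 0.0451. Defa and Klk (0.118 each) and Prl (0.144), which lie in tandem clusters, did not pass. Of the 365 pairs, 78 passed by Fisher's exact test and 34 by rotations. Reads lost in near-identical copies were not tested for Defa or Pramel.

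Long non-coding RNA genes lay in type 4 more often than other genes (3124 of 12322, 25.4% against 12.6%) and in type 1 less often (17.7% against 38.5%). Of 386 tRNA genes, 221 lay in type 3 (57.3%, adjusted p = 4.84e-26 by Fisher's exact test), and of 82 J segments of antigen receptor loci, 58 lay in type 4 (70.7%, adjusted p = 1.07e-27). V segments went the other way, with 8 of 374 in type 4 (2.14% against 16.0%), 183 in type 1 (48.9%) and 124 in type 5 (33.2%). Small nucleolar RNA genes lay in type 1 in 655 of 1276 cases (51.3%), and pseudogenes in type 5 in 1925 of 8797 (21.9% against 10.7%). These counts treat clustered genes as independent. Olfactory receptor genes were in type 5 on chromosome 2 in 249 of 287 cases (86.8%) and on chromosome 11 in 23 of 83 (27.7%), and on chromosome 4 12 of 24 lay in type 4. Type 1 vomeronasal receptor genes were in H2Aub type 1 in 113 of 124 cases on chromosome 7 (91.1%), but on chromosome 6 31 of 51 lay in H2Aub type 5 (60.8%). Of 121 type 2 vomeronasal receptor genes, 83 lay in H2Aub type 1 (68.6%) and 38 in H2Aub type 5 (31.4%). Differences between chromosomes were not tested.

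Hox genes, keratin genes and developmental transcription factors shared an excess in type 4, which tandem clusters counted as many genes, or gene length, could produce. With clusters counted once, Hox genes were still 86.1 percentage points above other genes (4 of 4, Fisher's exact adjusted p = 0.00274) and developmental factors 41.2 points (72 of 131, adjusted p = 3.2e-26), which argues against clustering for both. Against 10000 draws of genes of the same length deciles, developmental factors were 39.3 points higher (53.8% against 14.6%, 95% of draws 9.09 to 20.3%), which argues against gene length; this was not tested for Hox or keratin genes. For keratin genes, 53.6 points above other genes, the difference fell to 11.1 points with 1 of 4 clusters in type 4 (Fisher's exact adjusted p = 0.613), which is what clustering as the cause predicts, although on 4 clusters. With clusters kept whole it was 50.8 points by circular shifts (permutation adjusted p = 0.037) and 53.4 by rotations (permutation adjusted p = 0.00335), which goes the other way, so clustering stays open for keratin genes; no biological explanation was tested.

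Olfactory receptor genes in type 5 may reflect tandem clusters, short genes or reads lost in near-identical copies. With clusters counted once they were 16.5 points above other genes (18 of 77, Fisher's exact adjusted p = 5.17e-05), and against genes of the same length 39.7 points (55.7% against 16.0%, 95% of draws 15.0 to 17%). These values argue against clustering and gene length as the whole cause, although the excess fell from 48.7 to 16.5 points when clusters were counted once. Reads lost in near-identical copies stay open: of 8 members with no gene of the same symbol stem within 1 Mb, 12.5% lay in type 5 (Olfr370, named after its value was seen, interval 0.316 to 52.7%, Fisher's exact p = 0.437), too few to decide. The gene-free chromosome starts were 99.3% type 1 and 0.352% type 5. That goes the other way from lost reads giving type 5, although no read count was given for these starts. Neither sequence composition nor a biological explanation was tested.

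The 2-cell stage genes in type 1 might be explained in the same way. With clusters counted once they were 40.1 points above other genes (17 of 22, Fisher's exact adjusted p = 0.00147), which argues against clustering. Reads lost in near-identical copies stay open: the gene-free starts were 99.3% type 1, and of 6 members with no gene of the same symbol stem within 1 Mb, 33.3% lay in type 1 (Zfp352 and Ubtfl1; interval 4.33 to 77.7%, Fisher's exact p = 1). All 6 members were named after their values were seen, the other 4 being Duxf3 in type 2 and Zfp750, Arg2 and Spz1 in type 3. The share of other genes in type 1, 37.1%, lay inside the interval of these 6, and that of the whole list, 82.1%, lay above it. So few genes cannot decide the test, and no biological explanation was tested.

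A hypothesis set before that test was that type 5 covers more of gene-poor chromosomes. Over the 19 chromosomes, Spearman's rho between the share of type 5 and protein-coding genes per Mb was -0.565 (two-sided permutation p = 0.0126), and r stayed below 0 without chromosomes 7 and 11 (-0.375). This is consistent with the hypothesis, with the limit that the relation was not past the threshold for shares of the number of segments (rho = -0.304, adjusted p = 0.257).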
